A study of Triticum aestivum with 16 samples.

How the data were processed

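RNA from the top of the stem was hybridised to 16 Affymetrix wheat arrays, 1 biotin-labelled sample per array. Per the labels, a sample used 1 g of tissue, 7 µg of total RNA and stems taken about 2 days after heavy rain. The deposited values are intensities of probe sets on a linear scale. Per the submitters' processing notes, GCOS and RMA were used; their roles and versions are not given in the sources used here, and whether further scaling was applied stays unknown. The values ran from 3.08 to 31223.4, with array medians of 23.5 to 25, and were log2-transformed here without a pseudocount. No genome build is named in the sources used here.

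The table held 61289 probe sets, of which 110 control probe sets were left out of the tests. The platform annotation gave 1 gene symbol to 1273 probe sets, several to 0 and none to 59906. Symbols and synonyms were updated by Entrez gene through the RefSeq gene table of the assembly IWGSC CS RefSeq v2.1, where 1272 matched, and 200 probe sets had a synonym or a symbol other than a LOC number. That table was used for names and for which genes neighbour each other.

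Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per line, 8 residual degrees of freedom and an empirical Bayes prior of 6.08. The moderated F test asked whether the 8 line means were equal, and contrasts set each line against the mean of the other 7 and took the 28 pairs. Adjusted p-values follow Benjamini and Hochberg over all tested probe sets within a contrast, with a threshold of 0.05. Named genes followed a rule set before the data were examined, as were the 24 gene lists and most alternatives: for the F test the 10 named probe sets with the widest distance between line means among those past the threshold, 1 per gene, and the 2 widest unnamed; for each line the 2 highest and 2 lowest named; and from lists of carbohydrate genes up to 4 members, from the other lists up to 2.

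A list was scored per array as the mean of its centred log2 values. The test was an exact permutation test over all 2027025 pairings of 16 arrays, one-sided for a larger share of variation between lines. Of the 24 lists, 3 had at least 3 named probe sets and were tested, 8 had 1 or 2, and 13 had none. A further 13 lists were built from the gene synonyms after the annotation and first results had been read. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for lists and permutations.

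The model was tested on simulated data with the means and variances of the 61179 probe sets. Of 100 probe sets shifted by 1 log2 unit in 4 lines, 81 were recovered by the F test, and of 100 shifted by 2 log2 units in 1 line, 94, with 9 false calls. For 1 line against the other 7, 96 of 100 shifted by 2 were recovered, with 10 false calls. The shifted probe sets were drawn from the brighter ones and the noise was independent between probe sets. Recovery among dimmer probe sets, or with variation shared between probe sets, was not examined. The list test called 1 of 40 simulated lists of 6 probe sets without line differences, and 40 of 40 with line differences of SD 1 log2 unit. Smaller line differences were not simulated for lists, so the power to detect them is unknown.

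The labels call the replicates field replicates without saying how they were laid out or sampled, so p-values measure only the spread between these samples, which may be partly technical. Alternatives were the replicate number as a block, quantile normalization again, centring on medians, the brighter probe sets alone, probe sets of unshared design alone, a trended robust prior, the ordinary F test, a minimum size of 1 log2 unit, median and z-score list scores, and leaving out each array. A covariate of histone level and leaving out SB3 and SB165 were added after seeing the data.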

Results

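Stem RNA was measured on 16 arrays from 8 recombinant inbred wheat lines descended from the cross of Seri M82 with Babax, grown in the field without irrigation. The lines were SB3, SB10, SB57, SB62, SB69, SB109, SB165 and SB169, each with 2 field replicates, and a sample pooled the upper stem, with its leaf sheath, of 7 to 8 main stems at anthesis. By the title of the series, the study concerned how stem storage of water-soluble carbohydrate differs between genotypes. The labels used here give neither the carbohydrate content of a line nor a class of high or low content, so each line was set against the others. Each array held 61179 probe sets besides the controls, and the median intensity per array lay between 23.5 and 25. With 2 arrays per line, the number of arrays limits the precision.

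The first comparison asked which transcripts differed between the 8 lines. The widest difference of a named gene was in LOC543445, for which the tables give no common name. It averaged 9.64 ± 0.09 (SD, n = 2) log2 units in SB3 and 3.48 ± 0.11 in SB62, a distance of 6.16 log2 units (limma adjusted p = 3.4e-08). Its mean was also high in SB10 at 9.61, SB165 at 9.01 and SB169 at 8.79, and low in SB57 at 3.55, SB109 at 3.9 and SB69 at 4.83. The small heat shock protein gene hsp16.9A (LOC543277), of a family of chaperones, averaged 7.14 ± 0.96 in SB165 and 2.36 ± 0.15 in SB57, a distance of 4.78 log2 units (limma adjusted p = 1.7e-05). Its low lines lay near the bottom of the scale. Where the lowest line lay below the median of the arrays, as for these genes, distances are given in log2 units and not as a fold. LTP3 (LOC543095), which encodes a lipid transfer protein, spanned 19.2-fold, from 9.83 ± 0.1 in SB10 to 5.56 ± 0.22 in SB165 (limma adjusted p = 8.1e-08). A second probe set of LTP3, with a mean of 12.4 log2 units over all arrays, spanned only 0.33 log2 units and did not pass (limma adjusted p = 0.74), so the probe sets of this gene disagreed.

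The other named genes with the widest differences had no common name in the tables. LOC543416 was highest in SB10, at 9.16 ± 0.27, and lowest in SB109, at 4.93 ± 0.16. LOC543287 stood at 8.03 ± 1.01 in SB10 and 3.81 ± 0.35 in SB169. LOC606356, LOC542961 and LOC543143 each had their highest mean in SB10 and their lowest in SB62, with distances of 3.89, 3.54 and 3.18 log2 units. Their means in SB3 lay close to those in SB10, at 7.41 against 7.61, 6.51 against 6.73 and 9.52 against 9.75. LOC780572 and LOC543313 also had their highest mean in SB10, by 14.8-fold over SB169 and 9.93-fold over SB57. Their limma adjusted p ranged from 0.00096 to 0.034. Other probe sets of LOC542961 and LOC606356 disagreed. For LOC542961 the other 4 spanned 0.16 to 0.38 log2 units and did not pass (limma adjusted p from 0.472 to 0.934), and for LOC606356 1 of the other 4 passed, at 3.67 log2 units between SB10 and SB62, while the rest spanned 0.3 to 1.04 (limma adjusted p from 0.328 to 0.832). With an intensity trend and a robust prior, the calls of LOC543416 (limma adjusted p = 0.19), LOC606356 (0.15), LOC780572 (0.27), LOC542961 (0.22), LOC543143 (0.15) and LOC543313 (0.057) were lost. With the ordinary F test, without pooled variance, LOC543287 (adjusted p = 0.11 in limma's fit) and these other genes (0.13 to 0.35) did not pass. The call of LOC780572 was also lost when any single array of SB10, SB57, SB62, SB69, SB109 or SB169 was left out, at distances of 3.67 to 4.44 log2 units. That of LOC542961 was lost without any single array of SB57, SB62 or SB169 and without SB10 replicate 2. That of LOC543416 was lost without any single array of SB10 or SB109. Replicates lay far apart in SB3 and SB165 for LOC780572 (SD 1.79 and 2.19), LOC606356 (1.55 and 1.71), LOC542961 (1.66 and 1.89) and LOC543143 (1.22 and 1.38). With the histone score as a covariate, the distance was 2.34 log2 units against 3.88 for LOC780572, which lost its call (limma adjusted p = 0.058), 2.53 for LOC606356, 2.07 for LOC542961 and 2.09 for LOC543143. The distance narrowed less for LOC543313, to 2.94 from 3.31. It did not narrow for LOC543416 (4.3 against 4.24), LOC543287 (4.55 against 4.22) or hsp16.9A (5.4 against 4.78). The 2 widest differences among probe sets without a gene name were 7.76 log2 units, between SB109 and SB165 (limma adjusted p = 2e-04, and 0.065 with the ordinary F test), and 6.79, between SB169 and SB109 (limma adjusted p = 1.2e-05). Replicates of the first lay far apart in SB10 (SD 4.04), and those of the second in SB69 (SD 2.62).

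**Figure D1:**
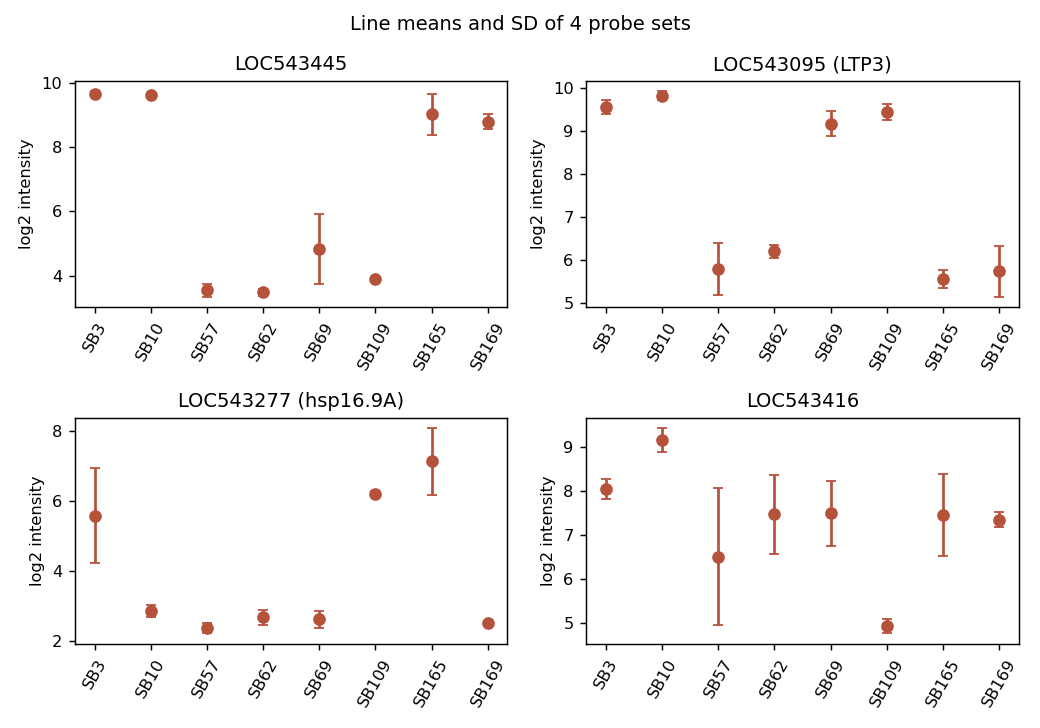
Line means of log2 intensity (vertical axes) for 4 named genes in the 8 lines (horizontal axes), with bars of 1 SD over 2 field replicates. LOC543445 lies between 8.79 and 9.64 in SB3, SB10, SB165 and SB169 and between 3.48 and 4.83 in SB57, SB62, SB69 and SB109.

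Among the probe sets whose gene has a common name, 10 passed, and they were listed after their values were seen. Of these, the alternatives were run only for hsp16.9A, LTP3 and, in SB10 against the other lines, TBP1. How far the calls of the others depend on the fit or on single arrays was not examined. The thionin gene THI1.1 was highest in SB165, at 5.91 ± 0.49, and lowest in SB62, at 4.05 ± 0.33, by 1 of its 2 probe sets. The other probe set spanned 0.34 log2 units (limma adjusted p = 0.89), so they disagreed. THI1.2 was highest in SB165 and lowest in SB3 (1.84-fold). PR5, a thaumatin-like protein gene, was 3.35-fold higher in SB169 than in SB69 (limma adjusted p = 0.049). Both probe sets of the xylanase inhibitor XIP-I were highest in SB10 and lowest in SB57, by 2.87-fold and 2.51-fold. For the alpha-tubulin gene TUBA, 1 of 2 probe sets spanned 3.55-fold, from 9.12 ± 0.56 in SB10 to 7.29 ± 0.41 in SB62, and the beta-tubulin gene tubb2 spanned 1.98-fold between SB10 and SB169. TBP1, the TATA-binding protein of the general transcription machinery, was lowest in SB10, at 6.72 ± 0.13, and highest in SB169, at 7.57 ± 0.16.

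In all, 2276 of 61179 probe sets, or 3.72%, differed between the lines by limma's moderated F test at an adjusted p of 0.05. The median distance between the highest and the lowest line was 1.26 log2 units among them, 1594 reached 1 log2 unit and 212 reached 3. Of the 1273 probe sets with a gene symbol, 95 were among the 2276. Without moderation of the variances the ordinary F test gave 700, and without SB3 replicate 1 the moderated test gave 3615. When both lines whose replicates lay farthest apart in histone level, SB3 and SB165, were left out, 3753 passed.

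The second comparison set each line against the mean of the other 7. These contrasts share arrays and are not independent. LOC543445, high in some lines and low in the rest, recurs in each of them. SB10 stood apart by 661 probe sets higher and 276 lower, and SB62 by 248 higher and 650 lower. SB10 had LOC543445 higher by 3.44 ± 0.28 log2 units (SE) and LOC543287 higher by 2.55 ± 0.37, with LOC780687 at -1.84 and TBP1 at -0.55. The SE reflects the spread of replicates and not that between the other lines, whose means of LOC543445 had an SD of 2.83. It is moderated and pooled over all 8 lines, so it can understate the spread of a line whose own replicates lie apart. For LOC543287 the 2 replicates of SB10 had an SD of 1.01. SB62 had LOC542771 higher by 0.66 ± 0.13 and LOC542837 higher by 0.46 ± 0.1, with LOC543445 at -3.56 and LOC606356 at -2.46. SB3 differed by 371 higher and 260 lower probe sets, with LOC543445 at 3.47 and LTP3 at 2.16 above the others, and LOC543287 at -1.87 and LOC543111 at -1.26. SB169 differed by 421 higher and 257 lower, with LOC543445 at 2.51 and LOC543422 at 1.42, and LOC543287 at -2.27 and LTP3 at -2.2.

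SB165 differed by 244 higher and 167 lower probe sets. Its hsp16.9A exceeded the other lines by 3.6 ± 0.36 log2 units and its LOC543445 by 2.75, whereas LTP3 stood at -2.4 and LOC542911 at -0.68. The pooled SE does not show that the 2 replicates of hsp16.9A in SB165 had an SD of 0.96. SB109 had 213 higher and 250 lower, with hsp16.9A at 2.55 ± 0.36 and LTP3 at 2.04, and LOC543445 at -3.09 and LOC543416 at -2.71. SB69 had 206 higher and 468 lower, with LOC543111 at 1.76 ± 0.12 and LTP3 at 1.73, and LOC543445 at -2.03 and hsp16.9A at -1.59. SB57 had 360 higher and 279 lower, with LOC780687 at 1.63 ± 0.35 and LOC100049053 at 0.73, and LOC543445 at -3.49 and LTP3 at -2.14. The limma adjusted p of these genes ranged from 5.3e-06 to 0.049. Other probe sets of some of them did not pass the F test between lines, namely 1 of LOC543111, at 0.45 log2 units (limma adjusted p = 0.359), 1 of LOC780687 (0.113), 2 of LOC543422 (0.14 and 0.161) and 3 of LOC542771 (0.0523 to 0.867). With an intensity trend and a robust prior, 8 of these differences did not pass, with a limma adjusted p from 0.079 to 0.22: LOC780687 in SB10 and SB57, LOC543287 in SB3 and SB169, LOC543422 in SB169, LOC543416 in SB109, LOC606356 in SB62 and hsp16.9A in SB69. With the histone score as a covariate, LOC780687 in SB57 (limma adjusted p = 0.1) and SB10 (0.054), LOC543287 in SB3 (0.11), TBP1 in SB10 (0.087) and LOC542837 in SB62 (0.052) did not pass, nor did TBP1 in SB10 after centring on medians (0.05 after rounding). Several calls also ended without single arrays, with a limma adjusted p from 0.058 to 0.57 for TBP1 in SB10, 0.053 to 0.49 for LOC542837 in SB62, 0.055 to 0.45 for LOC780687 in SB57, 0.051 to 0.5 for LOC606356 in SB62 and 0.061 to 0.33 for hsp16.9A in SB69. Without SB62 replicate 1, LOC542771 stood at 0.44 (limma adjusted p = 0.24), and without SB69 replicate 2, LOC543445 stood at -1.25 (0.062) and LTP3 at 1.52 (0.061) in SB69. LOC542911 in SB165 did not pass without SB165 replicate 1 (limma adjusted p = 0.13), LOC543287 in SB10 without SB10 replicate 1 (0.11), and without either of the line's own replicates LOC100049053 in SB57 (0.17 and 0.18) and hsp16.9A in SB109 (0.053 and 0.067) did not. Without 1 of the line's own replicates, LOC780687 in SB10 (0.11 and 0.34), LOC543416 in SB109 (0.12 and 0.19), LOC543422 (0.094 and 0.57) and LOC543287 (0.07 and 0.23) in SB169, and LOC543287 in SB3 (0.61 without replicate 2) did not pass either. Leaving out 1 array moved the total of each line by over 1.5 times, and for SB3 it ranged from 191 without its replicate 2 to 2576 without its replicate 1.

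**Figure D2:**
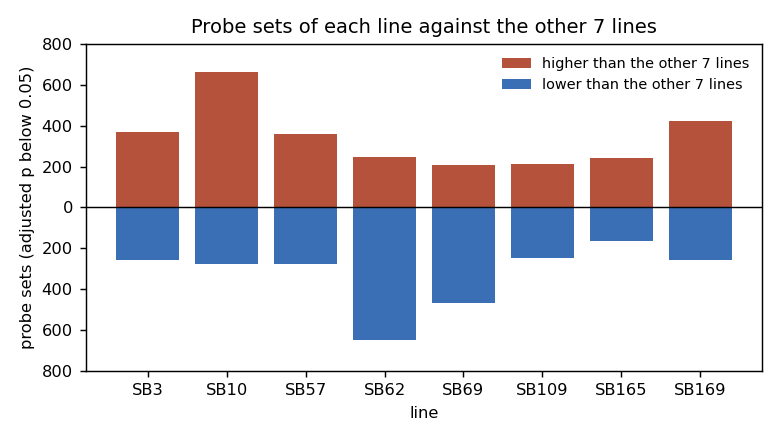
Number of probe sets (vertical axis) past a limma adjusted p of 0.05 in each line (horizontal axis) against the mean of the other 7, higher above the zero line and lower below it. SB10 has the most higher probe sets, 661, and SB62 the most lower, 650.

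The third comparison took the lines 2 at a time. Over the 28 pairs the median was 502 probe sets. The lowest number was 242, between SB57 and SB109, and the highest was 1727, between SB10 and SB62. Both numbers depended on single arrays. Between SB57 and SB109 there were 155 without SB57 replicate 1, 120 without SB57 replicate 2, 135 without SB109 replicate 1 and 156 without SB109 replicate 2. Between SB10 and SB62 there were 774 without SB10 replicate 1, 744 without SB10 replicate 2, 1083 without SB62 replicate 1 and 555 without SB62 replicate 2, with 1115 when probe sets of shared design were left out and 891 with the histone score as a covariate.

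**Figure D3:**
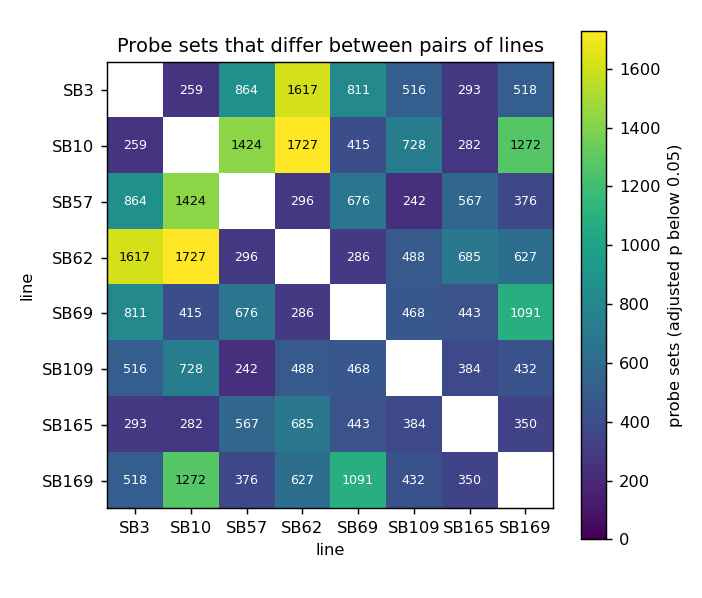
Number of probe sets past a limma adjusted p of 0.05 for each pair of the 8 lines (both axes), as number and colour. The numbers run from 242 for SB57 with SB109 to 1727 for SB10 with SB62.

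Among the gene lists of carbohydrate metabolism, only fructan hydrolysis had enough named probe sets for a test. Fructan exohydrolases release fructose from stored fructan. The gene 6-FEH had probe sets at 6.74 ± 0.12 log2 units in SB169 and 5.24 ± 0.21 in SB165 (limma adjusted p = 0.19), and at 7.27 ± 0.07 in SB169 and 5.72 ± 0.95 in SB109 (limma adjusted p = 0.28). Its remaining probe set spanned 0.41 log2 units (limma adjusted p = 0.75). The 1-FEHw2 gene lay at 11.26 ± 0.05 in SB62 and 10.68 ± 0.13 in SB169 (limma adjusted p = 0.14). None of the 4 passed over all probe sets, and 3 passed when adjusted over the list alone. Both wide probe sets of 6-FEH were among these 3. Of all 61179 probe sets, 9305 had an F test p under 0.05 before adjustment, so passing over so short a list is weak evidence. The mean score of the list ran from 0.44 ± 0.13 in SB169 to -0.3 ± 0.25 in SB165. The exact permutation test over all pairings of the 16 arrays detected no difference between the lines (one-sided, exact p = 0.207, adjusted p = 0.31). The score averages unlike profiles, since SB169 was highest for the first probe sets of 6-FEH and lowest for 1-FEHw2.

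Single members of other carbohydrate lists are given as values. The invertase gene IVR1 lay between 2.65 and 3.13 in line means, near the bottom of the scale. The starch synthesis gene AGP-S, a subunit of ADP-glucose pyrophosphorylase, lay between 8.86 and 9.01, and waxy, a starch synthase, between 4.41 and 4.7. No probe set was named for fructan synthesis, so its planned correlation with the other lists was not computed. The array's control probe sets for sucrose synthase, which cleaves sucrose, gave line means from 10.79 in SB169 to 11.29 in SB10 at the 3' end (exact permutation p = 0.0382, adjusted p = 0.321 over 24 wheat control probe sets) and from 9.62 in SB169 to 10.27 in SB10 in the middle (exact permutation p = 0.0107, adjusted p = 0.257). At the 5' end they ran from 6.37 in SB165 to 7.07 in SB10 (exact permutation p = 0.429, adjusted p = 0.643).

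The photosynthesis list held 31 probe sets, of which 28 were of the Rubisco large subunit. None passed, over all probe sets or adjusted over the list alone, and the score spanned 0.14 log2 units between lines (exact permutation p = 0.72, adjusted p = 0.72). The seed storage and inhibitor list held 3 serpins, which spanned 0.2 to 0.45 log2 units, and none passed, over all probe sets or adjusted over the list alone (exact permutation p = 0.195, adjusted p = 0.31). In lists too small for a test, PR5 of the defence list and hsp16.9A of the heat shock list passed as given above. XTH, which remodels cell wall xyloglucan, ranged from 7.99 to 8.8 (limma adjusted p = 0.4), and the profilins of the pollen and anther list spanned 0.25 and 0.18 log2 units (limma adjusted p = 0.68 and 0.89). In the drought and cold list, COR410 spanned 0.27 and LEA1 0.36 log2 units, both near the bottom of the scale (limma adjusted p = 0.93 and 0.59). The probe sets of the peroxidase gene PER1 in the redox list spanned 0.24 and 0.36 log2 units (limma adjusted p = 0.91 and 0.8).

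Field replicates varied in themselves. Over probe sets, the median intraclass correlation was 0.14. Over the brighter probe sets, centred on their means, arrays of 1 line correlated with a median r of 0.51 and arrays of different lines with -0.12, values across genes, which are not independent replicates. The centring itself pulls r between lines towards negative values, and the highest r between arrays of different lines was 0.62. The closest array was the other replicate of the line for 13 of 16 arrays. SB169 replicates correlated best (0.69), and SB165 replicates least (-0.08). The first principal component held 41.1% of the variance and parted the replicates of SB3, at 11.4 and 64.7, and of SB165, at -12.7 and 40.3.

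**Figure D4:**
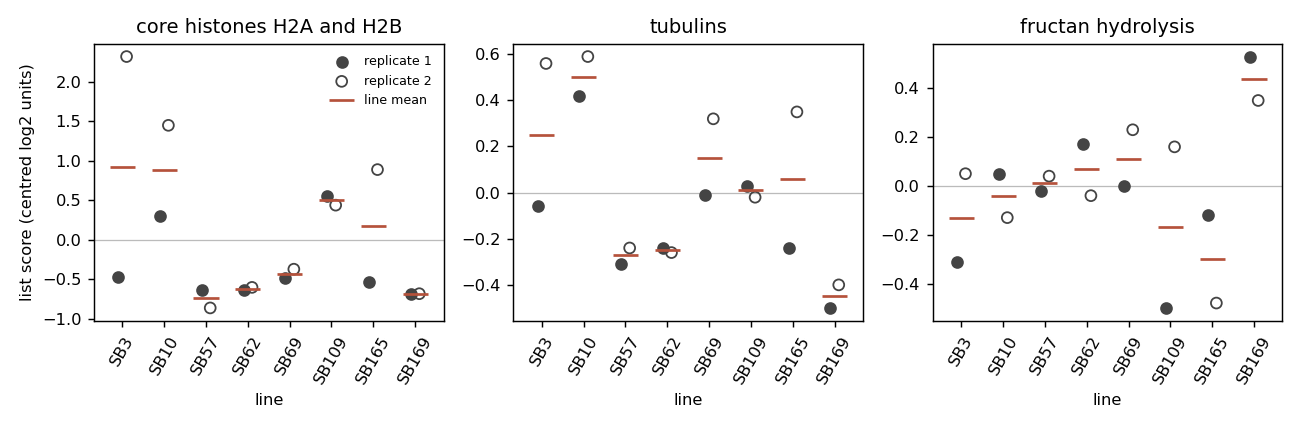
Mean centred log2 score (vertical axes) of 3 gene lists per line (horizontal axes), with filled and open points for the 2 field replicates and a bar for the line mean. The histone and tubulin lists were added after the results were seen; the histone replicates of SB3 lie at -0.47 and 2.32, and fructan hydrolysis is highest in SB169, at 0.44.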

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

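The added gene lists, the histone covariate and the fit without SB3 and SB165 were chosen after the results were seen; the others were planned. For the genes named by rule in a line against the mean of the others, no direction reversed under any alternative run for them. Distances between the highest and lowest line, counts and list tests carry no direction, so a reversal could not show in them. Whether the highest or lowest line of a gene changed was not examined. The 2276 probe sets that differed between lines became 700 with the ordinary F test, which lacks the pooled variance, and 3753 without SB3 and SB165 (the cause was not tested); 1 array left out gave 1583 to 3615. With a minimum size of 1 log2 unit, which removes smaller differences by construction, the totals were 249 for SB3, 364 for SB10, 250 for SB57, 374 for SB62, 189 for SB69, 214 for SB109, 196 for SB165 and 289 for SB169. With 1 array left out, the lone replicate being assumed to vary like the other lines, they ranged from 191 to 2576 for SB3, 303 to 1628 for SB10, 217 to 934 for SB57, 207 to 1335 for SB62, 124 to 824 for SB69, 204 to 512 for SB109, 240 to 419 for SB165 and 196 to 1056 for SB169. With the histone score as a covariate SB3 had 390 (the cause was not tested). The median over pairs was 378 to 637 with 1 array left out. The planned lists gave 0 calls in every setting run, and the added lists 0 to 1 with 1 array left out, the 1 being the gibberellin oxidases without SB10 replicate 2. The median intraclass correlation was 0.2 in the brighter probe sets. The correlations with fructan synthesis were not run, for lack of named probe sets. The labels say only that replicates are field replicates. Same-numbered arrays deviated together with r over 0.1 in 16 of 28 pairs of lines, with a median of 0.15 and a range from -0.37 to 0.63. A shared effect of the replicate number is therefore not excluded, though the main fit did not take the numbers as pairing. With the replicate block the count between lines was 2678, of which 2230 were shared with the 2276, and no total moved by over 1.5 times. No tested list changed its call, and neither did the genes named by rule for the F test or for single lines. The other named genes were not run under the alternatives. Calls named for 1 line were lost more often, per case, without an array of that line than without an array of another. Calls of named genes between lines were also lost without some single arrays, as given above. Signal near the bottom of the scale limits hsp16.9A, IVR1, LOC542961, LOC543445, LOC606356 and LOC543287.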

Other observations

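The added lists and their relations, and the tests of hybridisation spikes, mislabelling, independent segregation and pairings of the arrays, were chosen after the results were seen, as were the counts by transcript cluster, the number of members the sequence test did not cover and the lower limit for reading the test of neighbouring genes. None of the added lists differed between lines after adjustment. The lists of core histones H2A and H2B, which package newly replicated DNA, and of tubulins had the widest spread. The histone score ran from 0.92 ± 1.98 (SD, n = 2) in SB3 to -0.74 ± 0.17 in SB57, and 0 of its 18 probe sets passed (exact permutation p = 0.272, adjusted p = 0.354). Tubulins ran from 0.5 ± 0.12 in SB10 to -0.45 ± 0.07 in SB169, with 2 of 10 probe sets past the threshold (exact permutation p = 0.0581, adjusted p = 0.182; with the replicate block p = 0.0123 before adjustment). The methyl cycle and lignin list (SAHH and COMT1) ran from 0.36 ± 0.07 in SB10 to -0.4 ± 0.12 in SB57 (adjusted p = 0.182 by the exact permutation test). Thionins, with 2 of 6 probe sets past the threshold, late embryogenesis and dehydrin proteins and gibberellin 20-oxidases also had an exact permutation adjusted p of 0.182. For storage prolamins, amylase and trypsin inhibitors and anther raftins it was 0.312, for chloroplast proteins encoded in the nucleus 0.354, for translation factors and ribosomal proteins 0.373, for antioxidant enzymes 0.419 and for the Rubisco large subunit 0.742.

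Between the replicates of a line, differences in the histone score went with those in the tubulin score (Pearson r = 0.84, exact permutation p = 0.0118, adjusted p = 0.0403 over 5 relations; Spearman rho = 0.86, adjusted p = 0.0535; n = 8 lines) and against those in the antioxidant enzyme score (r = -0.78, exact permutation p = 0.0161, adjusted p = 0.0403; rho = -0.81, adjusted p = 0.0545). Without the 2 lines farthest from the median, r was 0.38 and -0.34, so both relations rest on those lines. For the fructan hydrolysis score no relation was detected (r = -0.02, exact permutation p = 0.966). The chloroplast proteins gave r = -0.53 and the methyl cycle and lignin list r = 0.62 (adjusted p = 0.224 and 0.183 by exact permutation).

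The replicates of SB3 and SB165 differed by 2.8 and 1.43 in the histone score, and those of SB10 by 1.15. A mislabelled array is argued against: on probe sets that split the other 14 arrays into 2 levels, the replicates shared their level in 91% of cases for SB3 and 89.8% for SB165, against at most 68.5% with an array of another line. Hybridisation stays open, since the spikes differed between replicates by 0.77 log2 units in SB3 and 0.46 in SB165, with 0.68 the highest of the other lines. RNA quality stays open too, with a difference in 3' minus 5' signal of 0.28 in SB165 and 0.04 in SB3 against at most 0.22, on control probe sets that are partly near the bottom of the scale. No biological explanation was tested, and a difference between field replicates in how far stem growth had gone could be examined next.

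Many probe sets fell into 2 levels. Of 482 with an empty interval of at least 1 log2 unit between arrays, 235 kept both replicates of every line on 1 side. A single division of the lines, SB3, SB10, SB165 and SB169 against SB57, SB62, SB69 and SB109, held 38 of the 235, among them LOC543445, and 36 were higher in the first 4 lines. Genes segregating independently are argued against, since 10000 draws gave at most 12, and by transcript cluster the division held 33 against at most 11. The next most frequent division held 16, also above the draws, so the excess is not particular to 1 division. The draws took all probe sets as independent, so they cannot tell 1 inherited segment from several. Sequence differences confined to single probe sets are argued against for the 15 members with other bright probe sets in their cluster, taken as a set. Their median r with 40 such probe sets was 0.66, against 0.1 at the 95th percentile of random bright probe sets set against 1 member. By cluster it was 0.65 against 0.28 over 11 clusters, and 0.59 against 0.31 over the 8 with probe sets of unshared design. A median does not clear each member, and a sequence difference shared by the probe sets of a cluster could give a like r. For the remaining 23 members sequence differences stay open. A candidate explanation is 1 large inherited segment, such as the wheat-rye chromosome translocation that Seri M82 is known to carry; the genotypes of the lines were not used here, and the 2 named members lie on different chromosomes of the reference.

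If lines inherit segments, neighbouring genes could share profiles. Over 29 pairs of called genes within 50 Mb in the reference, the mean absolute r of line means was 0.41, below the 0.45 median of 10000 shuffles of position, the bound set beforehand as counting against shared segments, but within their spread, from 0.37 at the 5th to 0.54 at the 95th percentile (permutation p = 0.77). This test detected no likeness of neighbours and, with 79 placed genes, leaves segments open. For the count of probe sets between lines, 1 of 100 pairings of the arrays, the real one, reached 2276, and the highest other gave 901. A chance pairing of arrays is argued against but not excluded, since only 100 of the 2027025 possible pairings were run.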
